A study of Mus musculus with 6 samples.

How the data were processed

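RNA from mouse sperm was measured on 6 two-colour microarrays, 3 from control males and 3 from males given cadmium chloride (CdCl2) in drinking water, each described in the labels as a biological replicate. Per the labels' protocols, RNA was extracted with Trizol, the IP RNA of each sample was labelled with the red dye Cy5 and the supernatant (Sup) RNA of the same sample with the green dye Cy3. The target of the immunoprecipitation is not given in the sources used here. No dye swap is described, so dye and fraction cannot be separated within an array. The dye term cancels in a comparison of the groups only if it was alike in both scans, which was not tested. The linear Cy5 factors in the file headers ranged from 14.4 to 21.3 on the control arrays and from 12.0 to 15.7 on the Cd arrays.

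The deposited scanner tables hold spot intensity values from Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity of each channel was background-subtracted and dye-normalized with a linear factor and a lowess term, per the file headers. The deposited log10 ratio of red over green was used only to check the processed signals. The authors' deposited series table holds log2 values. Each of its columns equalled the log2 processed IP signal minus 1 constant per array (11.09, 10.83, 11.07, 11.10, 10.77 and 11.19), with column medians of -2.87, -2.00 and -2.17 in the control arrays and -2.11, -1.81 and -2.36 in the Cd arrays. What the constant is stays unknown. That table carries no supernatant signal and was used only as an alternative for the RNA level.

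The IP over supernatant ratio was log2 of red over green processed signal, centred on each array's median. The RNA level was log2 of the summed processed channels minus each array's 75th percentile. The channels were dye-normalized first, so their weights in the sum are not the true amounts of the fractions. Spots with an outlier flag were removed, spots of a probe were averaged, and control spots, spike-ins and negative probes were left out. Probes entered the ratio test when well above background in both channels on at least 3 of the 6 arrays, and the level test when well above background in at least 1 channel on at least 3 arrays. Probes with a missing value on any array were then dropped. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, at a Benjamini-Hochberg adjusted p of 0.05, 2-sided. Single values per array were compared with an exact 2-sided permutation test, whose smallest possible p is 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

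On simulated data for the 23788 probes of the ratio test with 200 probes changed, 0% of 2-fold, 54% of 4-fold and 82.5% of 8-fold changes were recovered. For the 30518 probes of the level test the shares were 0%, 70% and 89.5%. With 8-fold changes, 6 unchanged probes were called for the ratio and 13 for the level. The simulated noise was normal and independent between probes, with each probe's own SD. It held no differences shared by the probes of an array or scan, so the shares may not carry over to the real comparison. The number of arrays limits the precision.

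Most probes carry only the array maker's identifiers in the sources used here. Of 50 Agilent catalogue probes with an accession, printed 10 times each, 45 matched a gene symbol in the RefSeq table of assembly GRCm38.p6, used for names only. The 26 gene lists fixed before the data were examined could not be tested: 2 of their genes had a named probe and no list had 5 measured genes, so the planned tests of lists and the list-wise description of IP enrichment were not run. Genes named in the text followed a rule fixed before the data were examined. It took probes with a known symbol past the threshold and, failing that, up to 6 per direction with the smallest unadjusted p among those whose 3 Cd values all lay on one side of the 3 control values, said not to have passed. It also asked for up to 3 members of each list and for set genes such as Mt1 and Prm1, which have no named probe here. Genes named for their control IP enrichment were chosen after their values were seen. The values of 1 gene are not reported here, though it is included in the counts.

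The scan records put the 3 control arrays in 1 scan and the 3 Cd arrays in another, and positions on the slide overlap between the groups. A block for slide or scan could not be fitted, and batch and group cannot be told apart in any comparison. Alternatives covered background correction by normexp with offset 50. It used median signals because the tables analysed here hold no mean signal column, a departure from the plan. The median background-subtracted signal of an array was 2.66 to 8.19 in the IP channel and 3.45 to 7.79 in the supernatant. An offset of 50 thus draws log2 ratios and differences of dim probes toward 0 by construction. Other alternatives covered filters, normalization, scaling to 14 probes read as spike-ins from their names, variance models and a replicate block. The deposited log2 table and leaving out each array were also used.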

Results

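Sperm RNA was compared between male C57BL/6 mice that drank control water and males given 100 mg/L CdCl2 from 5 weeks of age for 10 weeks, with sperm taken at 15 weeks. Each group had 3 arrays. On each array the immunoprecipitated (IP) and supernatant RNA of 1 sample were hybridised together. A probe gives the ratio of the fractions and their summed signal, called the RNA level here. The channels were dye-normalized on each array before summing. The sum therefore does not weigh the fractions by their true amounts, and the level is not a direct measure of input RNA. The arrays differed in brightness. In the IP channel 28.3%, 42.1% and 44.9% of probes were well above background on the control arrays and 49.6%, 49.2% and 44.0% on the Cd arrays. In the supernatant channel the shares were 35.3%, 39.2% and 44.2% against 50.1%, 45.7% and 47.7%. Every Cd array lay above every control array in the supernatant channel (exact permutation p = 0.1, the smallest possible) but not in the IP channel (exact permutation p = 0.2). The groups were scanned separately, so scan and treatment cannot be told apart in what follows.

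The first comparison asked which RNAs shifted between IP and supernatant with Cd. No gene with a known symbol passed the test. Among 27 such genes measured in both channels, the log2 ratio was higher in Cd for 19 and lower for 8, and none passed when adjusted over the list alone (smallest adjusted p = 0.402). These counts were 24 and 3 with normexp and 23 and 4 with spike-in scaling, and 28 and 17 of 45 genes with no filter. Under the rule for named genes, Gpi1, the glycolytic enzyme glucose-6-phosphate isomerase, had the smallest unadjusted p. Its ratio was 1.43 ± 0.12 in control and 2.20 ± 0.34 in Cd (SD, n = 3 each), a limma log2 difference of 0.77 with a 95% interval from 0.16 to 1.38, unadjusted p = 0.0184 and adjusted p = 0.961. Acaa2, a mitochondrial thiolase of fatty acid oxidation, differed by 0.43 (SE 0.25). Dnajc11, a mitochondrial DnaJ-family protein, differed by -0.63 (SE 0.27). The 3 Cd values of each of these 3 genes lay on one side of the 3 control values, and none passed adjustment. With normexp the differences were 0.44 for Gpi1, 0.40 for Acaa2 and -0.09 for Dnajc11. Gsta4, a glutathione transferase of the fixed antioxidant list, differed by 0.26 (SE 0.32).

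**Figure D1:**
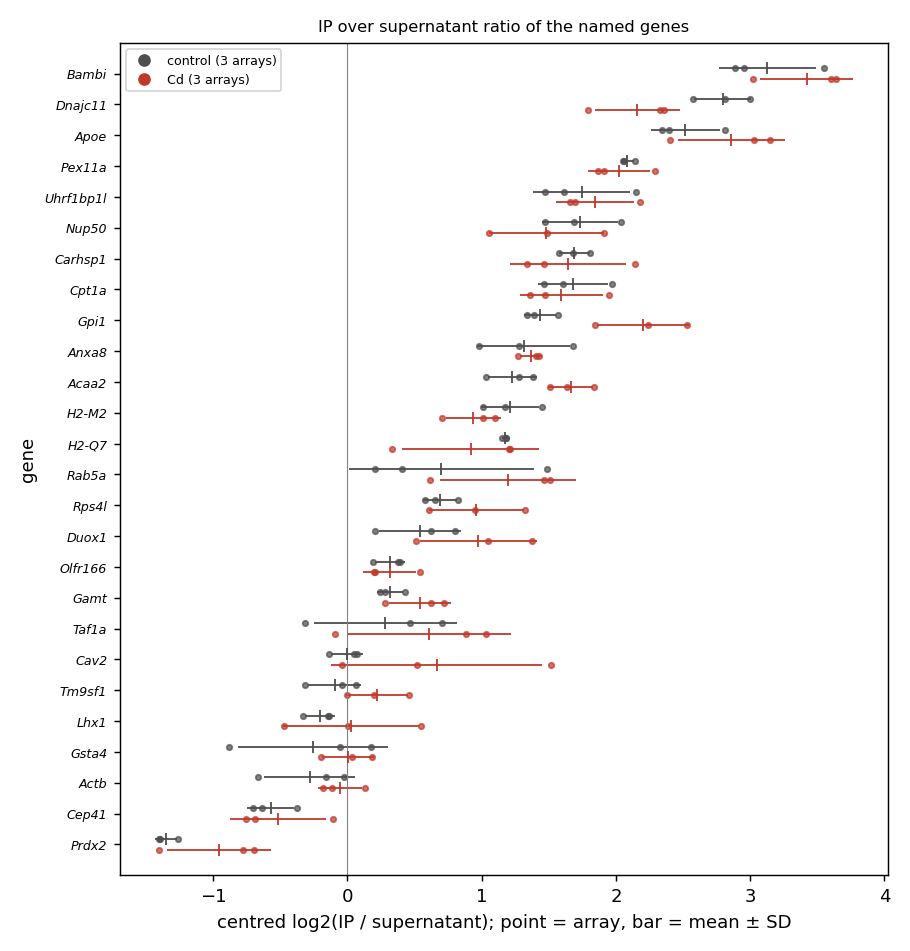
Centred log2 IP over supernatant ratio (x axis) of 26 genes with a known symbol (y axis), with points for arrays and bars for the mean ± SD of 3 control (grey) and 3 Cd (red) arrays. Control and Cd points of Gpi1, Acaa2 and Dnajc11 do not overlap, and no gene passed adjustment.

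Over all 23788 probes tested, limma called 1 probe higher and 0 lower in Cd. At an unadjusted p under 0.05, 629 were higher and 564 lower, 1193 in all against 1189 expected by chance. When each array was left out, 281 to 928 were higher and 321 to 714 lower. Control and Cd values did not overlap for 10.0% of probes, and chance gives 10%. The called probe, ASMM10EP3A100132869, has no gene name in the sources used here. Its log2 ratio rose from -3.17 ± 0.48 to 0.29 ± 0.15 (SD, n = 3 each), a limma log2 difference of 3.46 (SE 0.30, adjusted p = 0.0322). The supernatant intensity was 1267 ± 166 in control and 155 ± 68.4 in Cd, while the IP intensity was 148 ± 53.9 and 195 ± 102 and was not well above background on control replicate 1. The summed level of this probe differed by -2.35 (SE 0.35, limma adjusted p = 0.42). The call held without control replicate 1 (adjusted p = 0.0422). It was lost without each of the other arrays (adjusted p from 0.0994 to 0.518), where the log2 difference stayed between 3.40 and 3.65. It was also lost with normexp background correction (log2 difference 1.11, adjusted p = 0.349), whose offset shrinks differences of dim probes by construction. With normexp 74.8%, and with spike-in scaling 79.6%, of the probes at an unadjusted p under 0.05 were higher in Cd, against 52.7% in the main setting, 47.1% with no filter and 44.2% with no moderation of the variance. The share ranged from 46.7% to 62.0% when each array was left out.

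In control sperm, 19 of the 27 genes lay above the array median in the IP ratio and 8 below. The ratio was 3.13 ± 0.36 (SD, n = 3) for Bambi, a pseudoreceptor of TGF-beta signalling, 2.79 ± 0.21 for Dnajc11 and 2.52 ± 0.26 for Apoe, a lipid-carrying apolipoprotein. Pex11a, a protein of peroxisome proliferation, was at 2.08 ± 0.05. On the supernatant side were Prdx2, an antioxidant peroxiredoxin, at -1.35 ± 0.08, and Cep41, a ciliary protein, at -0.57 ± 0.18. These signs were the same with normexp, loess and spike-in scaling. The order of the genes named here changed with normexp, and sizes moved with normexp and spike-in scaling. With normexp the ratio was 2.70 for Apoe, 1.63 for Bambi, 1.57 for Pex11a, 1.14 for Dnajc11, -0.26 for Cep41 and -1.16 for Prdx2, and with spike-in scaling it was -1.15 for Cep41. Dye and fraction are confounded in these values, and no test was made.

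The second comparison asked whether RNA levels differed. Of 36 genes with a known symbol, 8 had a higher and 28 a lower mean level in Cd, and none passed over all probes or when adjusted over the list alone (smallest adjusted p = 0.0986). The genes named by the rule were all lower in Cd. Chgb, a secretory granule protein, differed by -1.83 (SE 0.48, unadjusted p = 0.0052, limma adjusted p = 0.441), and Mbp, myelin basic protein, by -3.01 (SE 0.80, limma adjusted p = 0.441). Both were dim: Chgb was well above background in the IP channel on 3 control arrays and 1 Cd array and on 0 arrays in the supernatant, and Mbp on 3 and 2 in the IP channel. Dnajc11 differed by -0.51 (SE 0.18), Tm9sf1 by -0.39 (SE 0.18), Ppara, a nuclear receptor of lipid catabolism, by -0.39 (SE 0.19) and Alkbh4, an AlkB-family dioxygenase, by -0.37 (SE 0.18). In the supernatant, Ppara and Alkbh4 were each well above background on 0 control arrays and 1 Cd array, so their level rests mainly on the IP signal. For Gpi1 the level difference was 0.23 (SE 0.20) and for Gsta4 -0.19 (SE 0.26). With normexp the differences were -0.34 for Chgb, -0.80 for Mbp, -0.15 for Dnajc11, -0.03 for Tm9sf1, -0.08 for Ppara and -0.15 for Alkbh4. With the supernatant channel alone the Dnajc11 difference was 0.03. When each array was left out, the difference ranged from -3.73 to -2.26 for Mbp and from -2.38 to -1.48 for Chgb. The count of genes lower in Cd was 21 with normexp and 31 with quantile normalization. It ranged from 23, without Cd replicate 3, to 30 when each array was left out. 8 named genes, among them Tyr, Il2 and E2f1, were not well above background in either channel on any array. Their scaled level in control and Cd was -3.85 and -4.65 for Tyr, -3.64 and -4.22 for E2f1, and -3.03 and -2.97 for Il2. The lowest scaled level counted as well above background averaged -2.44 on the control and -3.18 on the Cd arrays. How much of the Chgb and Mbp differences comes from this lower floor was not tested.

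**Figure D2:**
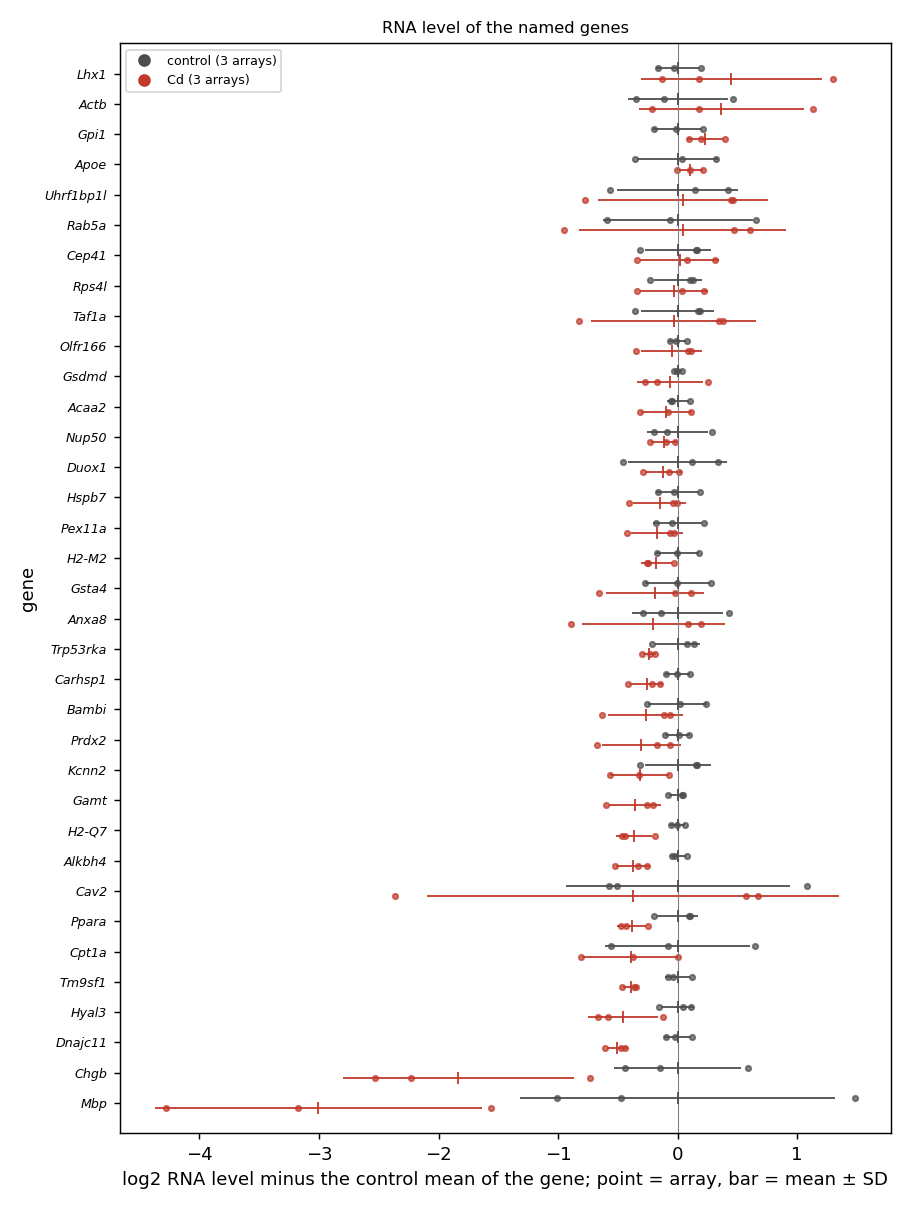
Log2 RNA level of 35 genes with a known symbol (y axis) relative to each gene's control mean (x axis), with points for arrays and bars for the mean ± SD of 3 control (grey) and 3 Cd (red) arrays. The Cd means of Mbp and Chgb are at -3.01 and -1.83, where the Cd signal was well above background on only 2 and 1 of the 3 arrays in the IP channel and on 0 in the supernatant, and no gene passed adjustment.

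Over all 30518 probes, limma called 0 higher and 0 lower in Cd (smallest adjusted p = 0.42). At an unadjusted p under 0.05, 1866 were higher and 1245 lower, 3111 in all against 1526 expected by chance. When each array was left out, 1039 to 2082 were higher and 817 to 1491 lower. Without control replicate 2 the counts were 1039 and 941. The groups did not overlap for 19.4% of probes, where chance gives 10%. Both chance values are averages and give no spread. Splits of the arrays that mix the groups gave from 393 to 3819 probes at an unadjusted p under 0.05. The excess over 1526 therefore does not by itself show an effect of Cd. The median 95% interval reached 0.55 log2 to each side of a probe's difference. Of the probes at an unadjusted p under 0.05, 60.0% were higher in Cd. The share was 77.8% with normexp, 93.8% with the deposited IP values and 9.96% with no filter on dim probes. In every other setting it lay between 52.2% and 68.5%, so the balance turned only with no filter. There the median difference over all probes was -0.26, against -0.003 in the main setting. The balance thus depended on the filter on dim probes, and it was close to even with quantile normalization (52.5%).

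The array carries 3 large probe series, named EP3A, EP3B and SM in the probe identifiers, whose meaning is not given in the sources used here. SM probes lay on the supernatant side on every array, with a median log2 ratio of -1.73 ± 0.26 in control and -1.67 ± 0.15 in Cd (SD, n = 3 each, exact permutation p = 0.8). The control value was -0.58 with normexp and -2.31 with spike-in scaling. Their median level was 0.06 ± 0.08 in control and 0.26 ± 0.16 in Cd, a difference of 0.20 (exact permutation p = 0.2). The groups overlapped, as Cd replicate 2, at 0.136, lay below control replicate 3, at 0.143. Without Cd replicate 3 the difference was 0.11, and with normexp it was 0.08. With the filter on all 6 arrays it was 0.24 (exact permutation p = 0.1, the smallest possible). At an unadjusted p under 0.05, 212 SM probes were higher and 36 lower in Cd. The level differences of EP3A and EP3B were -0.02 (exact permutation p = 0.3) and -0.004 (exact permutation p = 0.8).

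**Figure D3:**
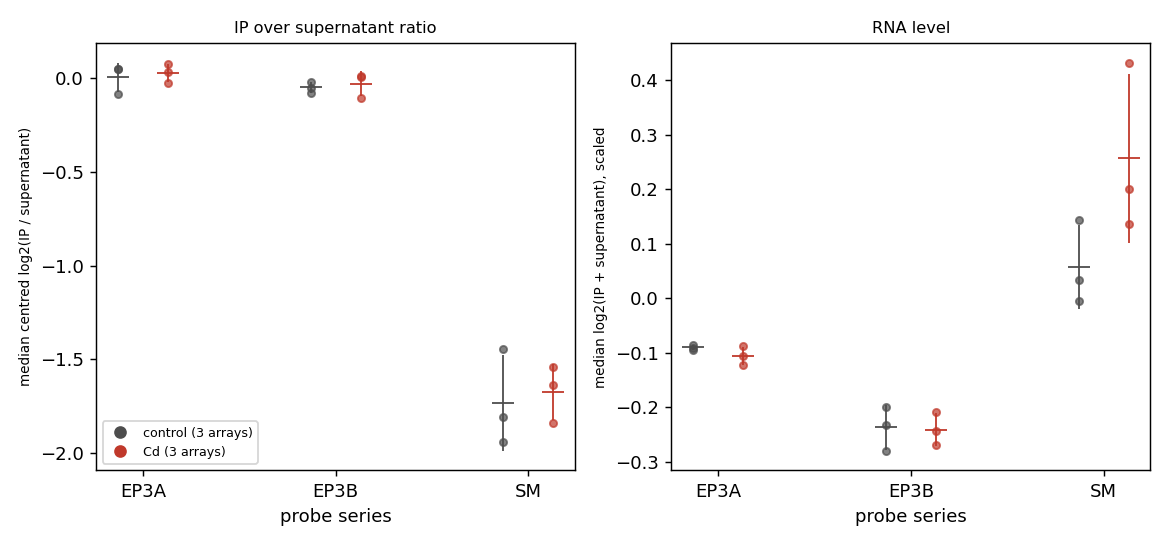
Median centred log2 IP over supernatant ratio (left) and median scaled log2 RNA level (right) of the probe series EP3A, EP3B and SM, with points for arrays and bars for the mean ± SD of 3 control (grey) and 3 Cd (red) arrays. SM has a ratio of -1.73 in control and -1.67 in Cd, and a level of 0.06 and 0.26.

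Across the whole array, the median uncentred log2 ratio was -0.04 ± 0.06 in control and -0.01 ± 0.01 in Cd (SD, n = 3 each, exact permutation p = 0.5). The processed signals were already dye-normalized on each array, which brings this median close to 0. It therefore cannot show whether IP enrichment as a whole differed between the groups. The 5′ minus 3′ log2 signal of the mouse Gapdh control probes was read as a possible sign of RNA integrity. In the IP channel it was -1.43 ± 0.05 in control and -1.86 ± 0.04 in Cd (exact permutation p = 0.1). In the supernatant it was -0.37 ± 0.21 and -0.66 ± 0.12 (exact permutation p = 0.1). All 3 Cd arrays lay below all 3 control arrays in both channels, in the supernatant by a narrow margin (-0.57 on Cd replicate 2 against -0.55 on control replicate 3). The supernatant difference was -0.29 and became -0.18 without control replicate 1. The fractions of the same control samples lay further apart, at -1.43 and -0.37, so the value does not track integrity alone. Dye and fraction are confounded there. Cd replicate 3 stood apart in RNA level, with 199 probes more than 4-fold above the median of the arrays, against 2 to 28 on each of the other arrays, and 77 more than 4-fold below it, against 4 to 21.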

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

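The tests of RNA from another organism and of RNA integrity below were chosen after the result was seen, and the test of array scaling before. Among 197 probes outside the main comparisons, 4 exceeded the highest control array by more than 1 log2 on a Cd array. The human GAPDH 5′ control probe did so by 1.99 and the rat GAPDH 5′ control probe by 1.18, both on Cd replicate 3. A probe read as a spike-in from its name did so by 1.30 on Cd replicate 1 and by 1.06 on Cd replicate 3, and another by 1.29 on Cd replicate 1.

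Cd replicate 3 also stood apart in its RNA level profile. Array scaling as the whole cause of its high probes is argued against, since 97.5% of its 199 probes more than 4-fold above the median of the arrays stayed so after quantile normalization. Its 77 probes more than 4-fold below the median were not tested in this way. RNA of another organism may contribute but stays open: 2 of the 4 human GAPDH and PGK1 control probes lay above all other arrays, and mouse RNA can bind these probes. Lower RNA integrity in this sample stays open too, because its mouse Gapdh 5′ minus 3′ difference lay below the other arrays in 1 of 2 channels. A difference between animals, or in the response to Cd, was not tested.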

How the results depend on the processing

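The joint exclusion of control replicate 1 and Cd replicate 3, and the alternatives for the SM series, Gapdh and control ratios, were chosen after seeing the data. For the ratio, the count of 1 probe higher in Cd became 0 with normexp, with the filter on all 6 arrays, with no filter, with the filter on 1 channel, with spike-in scaling, with the replicate block and without both doubted arrays. The filter on all 6 arrays removed the probe. Its log2 difference was 1.11 with normexp, 3.46 with no filter, the filter on 1 channel and the block, 3.59 with spike-in scaling and 3.16 without both doubted arrays, against 3.46 in the main setting. The count ranged from 0 to 1 when each array was left out. Loess, no centring and a variance trend gave 1. The unmoderated fit gave 1 higher and 1 lower, and the probe called in the main setting was not among them (adjusted p = 0.673). An unadjusted p under 0.05 with at least a 1.5-fold change gave 616 higher and 544 lower for the ratio, and 1276 higher and 733 lower for the level. Apart from that threshold, every alternative run for the level gave 0 and 0. The smallest limma adjusted p among them was 0.0565, without Cd replicate 3. It was 0.42 in the main setting and 0.234 without both doubted arrays. The array-wide ratio difference was 0.03 and ranged from -0.001 to 0.054 when each array was left out, falling below 0 without control replicate 1. These values come from dye-normalized signals and cannot show a shift of IP enrichment as a whole. For single genes, the level difference of Dnajc11 reversed to 0.03 with the supernatant alone. The normexp offset draws differences of dim probes toward 0 by construction. Beyond that, the cause was not tested in these cases. The replicate numbers did not pair the arrays (ratio deviations of same-numbered arrays correlated at -0.07, -0.05 and -0.12, and level deviations at -0.41, 0.43 and 0.00), and the block gave 0 calls for the ratio and 0 for the level. The median ratio difference over all probes was 0.04 and moved to 0.17 with spike-in scaling, and the median level difference moved to 0.29 in the deposited IP values. The slide block could not be fitted. Averages over probes of a gene, the series table for the ratio and all tests of gene lists were not run, as too few probes are named or the table holds 1 channel. Signal over background limits the ratio, as 24357 of 60691 probes passed its filter.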

Other observations

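All tests here were chosen after the result was seen, except the match of SM to EP3A probes. The 3 arrays against 3 allow 10 splits, too few to tell whether chance gives the counts. For the ratio 1 of 10 splits, the real one, gave as many as its 1 probe, and the highest other gave 0. For the level all 10 gave at least its 0 probes, and the highest other gave 36. For level probes at an unadjusted p under 0.05, 2 of 10 splits gave as many as the real 3111, and the highest other gave 3819. Both highest values came from the split that set control replicates 1 and 3 with Cd replicate 3 against the rest. The first principal component of the RNA level, the main axis of difference between the arrays, held 49.2% of the variance. It put Cd replicate 3 at -91.6, control replicate 1 at -26.3 and control replicate 3 at 10.4. Cd replicate 1 lay at 30.7, Cd replicate 2 at 31.3 and control replicate 2 at 45.5. That split thus follows this axis, on which the groups overlap. What lies behind the axis was not tested.

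Brightness shared by all probes of like summed level is argued against as the whole cause of the higher SM level on the Cd arrays. EP3A probes matched on mean RNA level shifted by 0.001. The SM shift exceeded theirs by 0.19, with every Cd array above every control array by a narrow margin (-0.04 on Cd replicate 1 against -0.06 on control replicate 3). The match did not cover the ratio, which was -1.73 for SM and 0.002 for EP3A in control. It therefore cannot decide on brightness of the supernatant channel, where every Cd array had more probes well above background than every control array. The SM shift was 0.21 in the supernatant alone and 0.25 in the IP alone. With normexp background correction the SM shift was 0.08. That setting also replaced the dye-normalized signals and added an offset, which draws differences of dim probes toward 0. How much each of these contributed was not tested. Cd replicate 3 alone stays open as a source, since without it the shift was 0.11 and Cd replicate 2, at 0.14, was level with control replicate 3. Slide or scan stays open, because 0 scans hold both groups. RNA integrity was not tested as a source and stays open, as the mouse Gapdh 5′ minus 3′ difference was lower on every Cd array than on every control array (-1.43 in control and -1.86 in Cd in the IP channel). An effect of Cd on this probe series may also contribute and cannot be told apart from the scan.

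For the single called ratio probe, movement of the dim IP signal alone is argued against as the cause. Its supernatant signal, well above background on all 6 arrays, changed by -3.34 log2. The IP signal changed by 0.08 log2 and was dim in both groups, and the summed level differed by -2.35. A loss of the RNA from both fractions, with the IP signal held near the floor, stays open. It cannot be told here from a shift between the fractions. Slide or scan stays open, with 0 scans holding both groups. A hypothesis is that Cd may lower this RNA in the supernatant fraction, which arrays with both groups in 1 scan would test.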
